A study of Homo sapiens with 6 samples.

How the data were processed

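Polyadenylated RNA of 2 human cell lines, NCI-H1650 and NCI-H1650Re, was sequenced in 3 libraries each; per the labels, RNA was extracted with miRNeasy and libraries were made with a BGI mRNA kit. The submitters' processing notes name HISAT2, Bowtie2, RSEM and DESeq2, without versions. They also name the mouse build mm10, whereas the deposited tables carry human Ensembl identifiers; the human build is not given in the sources used here. FPKM values per library and gene were computed by the authors and deposited for 12659 genes, of which 11909 carry an Ensembl identifier and 750 are new genes or have no name. How the new genes were defined and how the table was filtered is not given in the sources used here. Read counts were deposited by the authors only for the 860 genes they marked as regulated. The FDR of each gene, an adjusted p-value, was computed by the authors, per the file headers. The log2 fold change of each gene was also computed by the authors, per the file headers. FPKM of the 860 genes did not differ between the 2 deposited tables that hold them.

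Counts of all genes were not used here, so the main test was limma on log2(FPKM + 1) and not a count model. Genes with a mean of at least 1 FPKM in either line were kept, which left 11764, 727 of them without a name. A linear model with the line as its only term was fitted in limma with a variance trend, coded NCI-H1650Re minus NCI-H1650, and p-values were adjusted by the Benjamini-Hochberg method at 0.05. Values were taken as deposited, with no further scaling. Gene lists were tested with limma's camera at a preset correlation of 0.01, for the 28 of 30 lists with at least 5 tested members, and again with an estimated correlation and with fry. The lists held 690 symbols and were fixed before the data were examined, as were the comparison, the thresholds, the key genes and the other settings listed below. Symbols absent from the tables were matched through a RefSeq synonym. The lists described are those named in the report; some genes and lists fixed beforehand are not analysed here.

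Genes were named by a rule fixed in advance: the key genes; the 10 largest rises and 10 largest falls among genes past the threshold with no overlap between lines; and, per list, up to 4 members past the threshold with the largest change. The rule also allowed up to 2 members per list that did not pass. Those that were not key genes were left out of the text, apart from CALR and HSP90B1. That choice was made after seeing that most changes of sign under other settings came from such members. Values of some members that did pass, among them BGN, IFIT2, CCL5, CXCL2, TAPBP and SGK1, are not given below either. MX1 and the per-library VIM values were singled out after their values were seen. Counts of the marked genes were tested with edgeR and DESeq2, with library sizes taken from the ratio of counts to FPKM. Depth was estimated in the same way, from 243 genes for the ratio between libraries and 16 for the level, and was 22.3, 19.4 and 17.0 M fragments for NCI-H1650 and 20.3, 21.6 and 18.1 M for NCI-H1650Re. Pearson correlations of log2 values were 0.988 to 0.997 within NCI-H1650, 0.980 to 0.994 within NCI-H1650Re and 0.959 to 0.970 between lines. The first 3 principal components held 68.6%, 16.9% and 8.83% of the variance.

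Gene positions, GC content and transcript lengths came from GENCODE release 29 (GRCh38), matched by Ensembl identifier for 11909 genes (94.1%); 11035 tested genes had GC and length. Runs of neighbouring genes were sought with medians of 25 genes in order and a cutoff of 0.3 on the log2 scale, against 1000 shuffles of the genes. This search was chosen after the data were seen. So were the tests without both replicate 3 libraries, without genes in those runs, with GC and length removed, and with edgeR and DESeq2 on counts rebuilt from FPKM, transcript length and depth. The rebuilt counts were within 1 percent or 1 count of the deposited counts for 83.7% of values in 635 genes.

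On simulated data of 11764 genes, limma for NCI-H1650Re against NCI-H1650 recovered 50%, 92%, 100% and 98% of 50 genes planted at log2 changes of 0.5, 1, 2 and 3, with 8 false calls, 4.49% of its calls. Camera found the planted list and 0 of 27 others. Noise was drawn independently for each gene here, so the simulation could not show false list calls that come from correlated genes. The search for runs recovered 100% of the inner windows of 80 planted genes and called 3 windows elsewhere. The other settings fixed beforehand were pseudocounts of 0.1 and 0.01, no filter, a filter at 5 FPKM, median-of-ratios and quantile scaling, a replicate block, no variance trend and each library left out in turn. Analyses used R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15 and matplotlib 3.10.9.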

Results

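Polyadenylated RNA was sequenced from NCI-H1650, an established human lung adenocarcinoma cell line with an activating EGFR deletion, and from NCI-H1650Re, its derivative. The labels place the parental line before transformation (pre-LUAD) and the derivative after it (post-SCLC), and the comparison asks which genes changed between these states. Each line had 3 libraries, for 6 in all. Estimated depth was 22.3, 19.4 and 17.0 M fragments for NCI-H1650 replicates 1, 2 and 3, and 20.3, 21.6 and 18.1 M for NCI-H1650Re replicates 1, 2 and 3. The labels do not say that the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Levels below are FPKM, as mean ± SD of the 3 libraries of a line, and log2 changes are NCI-H1650Re minus NCI-H1650 on log2(FPKM + 1), which understates the change of low genes.

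Between NCI-H1650 and NCI-H1650Re, KRT19, a keratin of simple epithelia, fell from 754 ± 97.5 to 68.7 ± 41.8 FPKM. CDH1, which encodes E-cadherin, fell from 248 ± 9.16 to 141 ± 23.4, and CA9, a hypoxia-induced carbonic anhydrase, from 9.11 ± 2.72 to 0.0933 ± 0.0252 (n = 3 per line). GDF15, a stress-induced cytokine, rose from 2.32 ± 1.94 to 31.1 ± 3.75, and PSAT1, a serine synthesis enzyme, from 33.9 ± 2.40 to 108 ± 24.7. COL12A1, a fibril-associated collagen, rose from 4.86 ± 0.338 to 33.3 ± 4.48. Of 11764 genes tested with limma, 3587 passed a Benjamini-Hochberg adjusted p of 0.05, 1952 higher and 1635 lower in NCI-H1650Re. The share of rises was 54.4%, against 49.3% with median-of-ratios scaling, 48.3% and 49.1% with edgeR and DESeq2 on rebuilt counts, 48.8% without NCI-H1650Re replicate 2, 57.4% among genes with a group mean of at least 5 FPKM and 58.6% without genes in runs of shifted neighbours. Most changes were small: 149 genes rose and 211 fell by at least 1 on the log2 scale. The lines did not overlap for 5556 tested genes, 47.2% of them, against 10% by chance. Leaving out a single library gave 1785 changed genes without NCI-H1650 replicate 2, 1898 without NCI-H1650Re replicate 2 and 2386 without NCI-H1650 replicate 1. Without both replicate 3 libraries, which stood apart from the others of their lines, the count of genes changed was 5080.

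Among genes past the threshold whose lines did not overlap, the largest rises were those of GDF15 (log2 change 3.41), FAM133A (2.82), COL12A1 (2.54), the homeobox gene MKX (2.53), ADM2 (2.51), the proteoglycan CSPG4 (2.49), COL26A1 (2.28), KLHDC7B (2.18), TOX2 (2.08) and GPX3 (2.02). The largest falls were those of CASP14 (-3.66), KRT19 (-3.59), CA9 (-3.17), an unannotated locus that the authors named as a new gene (-3.15), LY6D (-3.07), the protease KLK5 (-3.06), the immediate early gene EGR1 (-2.97), CALB2 (-2.67), COL17A1 (-2.57) and TMPRSS13 (-2.54). Their limma adjusted p (Benjamini-Hochberg) ran from 3.94e-05 for TMPRSS13 to 0.0103 for KLHDC7B. COL12A1 lies at chromosome 6, 75084326 to 75206051, KRT19 at chromosome 17, 41523617 to 41528308, and CA9 at chromosome 9, 35673856 to 35681159 (GRCh38). KRT19 and other keratins have near-identical relatives or pseudogenes, and their values are uncertain to that extent. CA9 rested on 2 to 364 counts per library, and KRT19 on 1175 to 23267. MKX and CALB2 lie in runs of neighbouring genes that shifted together.

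**Figure D1:**
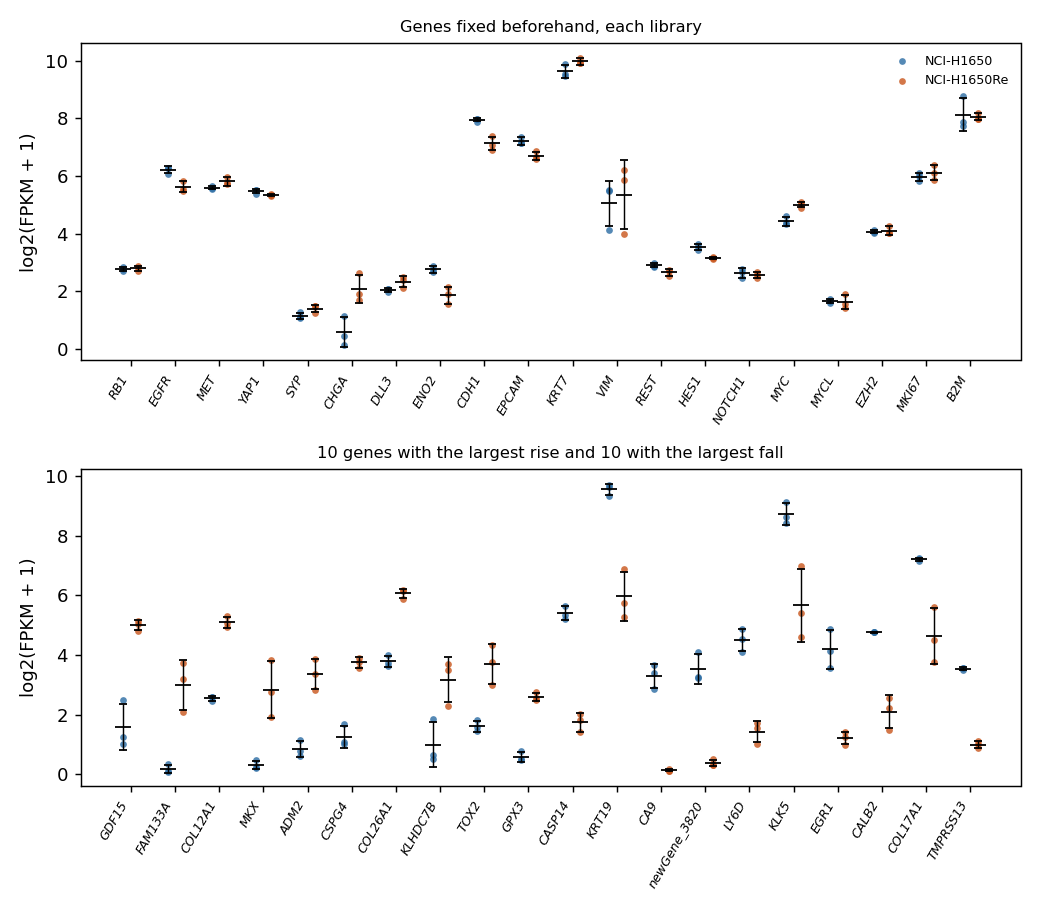
Expression of single genes in each library, as log2(FPKM + 1) on the vertical axis. Each point is 1 library, blue for NCI-H1650 and orange for NCI-H1650Re; black bars are the mean and SD of 3 libraries. The upper panel holds 20 genes fixed beforehand and the lower panel the 10 largest rises and 10 largest falls; KRT19 separates the lines, while VIM is lowest in replicate 3 of each line.

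Of 31 genes fixed beforehand for lung adenocarcinoma, small cell lung cancer and their transition, 20 were analysed; 2 rose, 5 fell and 13 did not pass. CHGA, the neuroendocrine granule protein chromogranin A, rose from 0.563 ± 0.590 to 3.39 ± 1.55 FPKM (log2 change 1.5, SE 0.31, limma adjusted p = 0.0101). MYC rose from 20.7 ± 2.47 to 31.3 ± 2.17. EGFR fell from 73.4 ± 6.23 to 48.6 ± 6.84 (log2 change -0.59, SE 0.11, limma adjusted p = 0.00718). CDH1 (-0.82), EPCAM (-0.50), the Notch target HES1 (-0.38) and ENO2 (-0.90), which encodes neuron-specific enolase, also fell. RB1, the tumour suppressor often lost in small cell lung cancer, was at 5.85 ± 0.324 FPKM in NCI-H1650 and 5.96 ± 0.446 in NCI-H1650Re. Its log2 change was 0.02, with a 95% interval from -0.16 to 0.21 and a limma adjusted p of 0.849. SYP was at 1.23 ± 0.159 and 1.65 ± 0.240, DLL3 at 3.13 ± 0.156 and 4.10 ± 0.695, REST at 6.48 ± 0.368 and 5.32 ± 0.467, YAP1 at 43.6 ± 2.43 and 39.6 ± 0.987, MET at 47.5 ± 1.38 and 55.5 ± 5.80, KRT7 at 800 ± 124 and 1012 ± 77.9, and none of them passed. Nor did NOTCH1, MYCL, EZH2, MKI67 or B2M. VIM, encoding vimentin, was at 45.1, 44.0 and 16.6 FPKM in NCI-H1650 replicates 1, 2 and 3 and at 57.6, 72.3 and 15.01 in those of NCI-H1650Re. Without NCI-H1650Re replicate 3, DLL3 (adjusted p = 0.00877), SYP (0.0446) and KRT7 (0.0484) passed limma, and without NCI-H1650 replicate 3 KRT7 did (0.0106). Without both replicate 3 libraries VIM (limma adjusted p = 0.00702), KRT7 (0.00215), DLL3 (0.0108), SYP (0.0198) and REST (0.0357) passed. REST also passed with median-of-ratios scaling (limma adjusted p = 0.0460) and with edgeR (0.0291) and DESeq2 (0.0181) on rebuilt counts, KRT7 with quantile normalization (0.0322) and DESeq2 on rebuilt counts (0.0415), and YAP1 with the latter (0.0431). VIM lies in a run of chromosome 10 genes that were higher together. An exact two-sided permutation test of 3 against 3 libraries cannot go below p = 0.1. It gave that value for each of the 7 genes that passed, and also for MET, YAP1, DLL3, KRT7 and REST, which did not. The lines did not overlap for any of these genes. The other 11 genes, among them NEUROD1, POU2F3, INSM1, NKX2-1 and SOX2, were not tested. They were absent from the deposited values or had a mean under 1 FPKM in both lines. How the deposited values were filtered is not given, so absence alone was not read as lack of expression.

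In the lower-going lists, glycolysis and hypoxia genes moved most uniformly. Of 26 tested members of the hypoxia and glycolysis list, 20 fell, none rose and 6 did not pass; adjusted over the list alone, 22 fell and 1 rose. EGLN3, a prolyl hydroxylase, fell from 23.9 ± 4.37 to 4.39 ± 2.76 FPKM, PFKFB4 from 13.7 ± 0.690 to 3.91 ± 0.539 and the mitophagy receptor BNIP3 from 33.0 ± 3.98 to 13.2 ± 1.14, beside CA9. The list's median log2 change was -0.60 (limma camera adjusted p = 1.20e-10, and adjusted p = 0.651 with an estimated correlation). Of 14 basal and squamous markers, 7 fell and 1 rose (adjusted over the list alone, 8 and 1); KRT15 fell from 9.33 ± 1.21 to 1.58 ± 0.707, the desmosomal DSG3 from 23.2 ± 5.32 to 6.49 ± 2.27 and KRT5 from 2.32 ± 0.604 to 0.0800 ± 0.01. KRT17 rose from 4.18 ± 3.47 to 15.5 ± 5.39, a call that ended without NCI-H1650 replicate 1 (limma adjusted p = 0.0665), NCI-H1650 replicate 2 (0.0692) or NCI-H1650Re replicate 2 (0.0702). That list's median log2 change was -0.75 (limma camera adjusted p = 0.00130, and adjusted p = 0.653 with an estimated correlation). Of 29 epithelial junction and keratin genes, 10 fell and none rose (adjusted over the list alone, 12 and 1). Without both replicate 3 libraries 14 fell and 3 rose (limma camera adjusted p = 0.000632 at the preset correlation). Besides KRT19 and CDH1, PROM2 fell from 23.4 ± 2.73 to 6.85 ± 2.14, P-cadherin CDH3 from 171 ± 5.76 to 68.9 ± 5.45 and the transcription factor ELF3 from 33.2 ± 3.74 to 17.6 ± 1.87 (list median log2 change -0.30, limma camera adjusted p = 0.00130, and adjusted p = 0.728 with an estimated correlation). CDH1 and CDH3 lie within a run of chromosome 16 genes that were lower together.

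Antigen presentation genes were also lower as a list: of 18 tested, 6 fell and 1 rose, the same counts adjusted over the list alone. The immunoproteasome subunit PSMB10 was at 20.3 ± 7.85 and 9.99 ± 0.786 FPKM, NLRC5, the class I transactivator, at 6.48 ± 3.10 and 2.01 ± 0.737, and the peptidase ERAP2 at 9.08 ± 1.87 and 4.39 ± 0.635. The median log2 change was -0.43 (limma camera adjusted p = 0.00674, and adjusted p = 0.728 with an estimated correlation). NLRC5 missed the limma threshold without NCI-H1650Re replicate 2 (adjusted p = 0.0512), and PSMB10 without NCI-H1650Re replicate 2 (0.0559) or NCI-H1650 replicate 2 (0.0512). The list's median was higher in replicate 3 than in the other libraries by 0.68 in NCI-H1650 and 0.34 in NCI-H1650Re on the log2 scale, and without NCI-H1650 replicate 3 the list's limma camera adjusted p was 0.116. Without both replicate 3 libraries 9 of 17 fell and 2 rose, and the list passed (limma camera adjusted p = 0.0299). Of its members, 10 lie in runs of neighbouring genes that shifted together. Over the other 8, 1 rose and none fell (limma camera adjusted p = 0.379). The runs were found from these same log2 changes, so leaving out their genes takes away members that shifted. The lost call therefore cannot tell why the list fell.

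In NCI-H1650Re the unfolded protein and integrated stress list was higher: of 25 tested members 13 rose and none fell (adjusted over the list alone, 14 rose). Without both replicate 3 libraries 16 rose and 4 fell (limma camera adjusted p = 0.00372 at the preset correlation). CHAC1, an ATF4 target, rose from 4.45 ± 1.14 to 17.6 ± 5.69 FPKM, the pseudokinase TRIB3 from 20.5 ± 5.55 to 67.6 ± 15.03 and asparagine synthetase ASNS from 12.5 ± 1.96 to 38.0 ± 8.60, besides PSAT1. These 4 genes belong to the amino acid response. Of the 12 members that did not pass, the chaperones CALR and HSP90B1 had the highest levels. Their log2 changes were -0.146 and -0.149 (limma adjusted p = 0.161 and 0.181). The list's median log2 change was 0.50 (limma camera adjusted p = 0.00131, and adjusted p = 0.728 with an estimated correlation). Of 19 MAPK output genes, 12 rose and 4 fell (adjusted over the list alone, 14 and 4), with the cytokine LIF from 1.86 ± 0.565 to 8.28 ± 1.21, ETV5 from 2.71 ± 0.387 to 10.9 ± 1.11 and FOSL1 from 8.14 ± 2.26 to 27.4 ± 10.1, while EGR1 fell from 18.5 ± 9.02 to 1.34 ± 0.345. The list's median log2 change was 0.67 (limma camera adjusted p = 0.0138, and adjusted p = 0.728 with an estimated correlation). Among genes with a group mean of at least 5 FPKM the median was 0.75 and the call was lost (limma camera adjusted p = 0.107).

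YAP and TEAD targets rose in 10 of 21 tested members and fell in none (adjusted over the list alone, 12 rose), with NT5E from 5.65 ± 1.19 to 12.2 ± 1.42 FPKM, AJUBA from 10.5 ± 1.30 to 20.6 ± 1.95 and DLC1 from 3.78 ± 0.374 to 7.53 ± 0.386. CTGF rose from 6.05 ± 0.531 to 15.3 ± 7.44, but missed the limma threshold without any 1 library except NCI-H1650Re replicate 1, with adjusted p = 0.111, 0.135 and 0.0887 without NCI-H1650 replicates 1, 2 and 3, and 0.153 and 0.0794 without NCI-H1650Re replicates 2 and 3; it was 0.0789 without both replicate 3 libraries and 0.05003 to 0.0551 with no filter, other scalings, no variance trend or GC and length removed. The list's median log2 change was 0.39 (limma camera adjusted p = 0.00130, and adjusted p = 0.651 with an estimated correlation). Of 12 genes of the list NF-kB and inflammatory cytokines, 5 rose and none fell (adjusted over the list alone, 7 rose); the NF-kB subunit RELB rose from 2.73 ± 1.74 to 11.7 ± 3.56. IL6 rose from 9.05 ± 5.08 to 24.8 ± 6.73, with limma adjusted p = 0.0582 without NCI-H1650 replicate 1, 0.0614 without NCI-H1650 replicate 2 and 0.0635 without NCI-H1650Re replicate 2. The list's median log2 change was 0.53 (limma camera adjusted p = 0.0255, and adjusted p = 0.728 with an estimated correlation). It missed the limma camera threshold without NCI-H1650 replicate 1 (adjusted p = 0.0933), NCI-H1650 replicate 2 (0.0590), NCI-H1650Re replicate 2 (0.0691) or NCI-H1650Re replicate 3 (0.0501), and among genes with a group mean of at least 5 FPKM (0.0715). In all, 8 of 28 lists with at least 5 tested members passed limma camera at its preset correlation and 0 with an estimated correlation, where 2 had an unadjusted p under 0.05; fry called 7, 4 of them among the 8, and others included drug efflux (limma fry adjusted p = 0.00425) and the NRF2 list (0.0110). Of the 10 ways to split the 6 libraries into 3 and 3, 5 gave at least 8 lists past camera, the real split included.

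**Figure D2:**
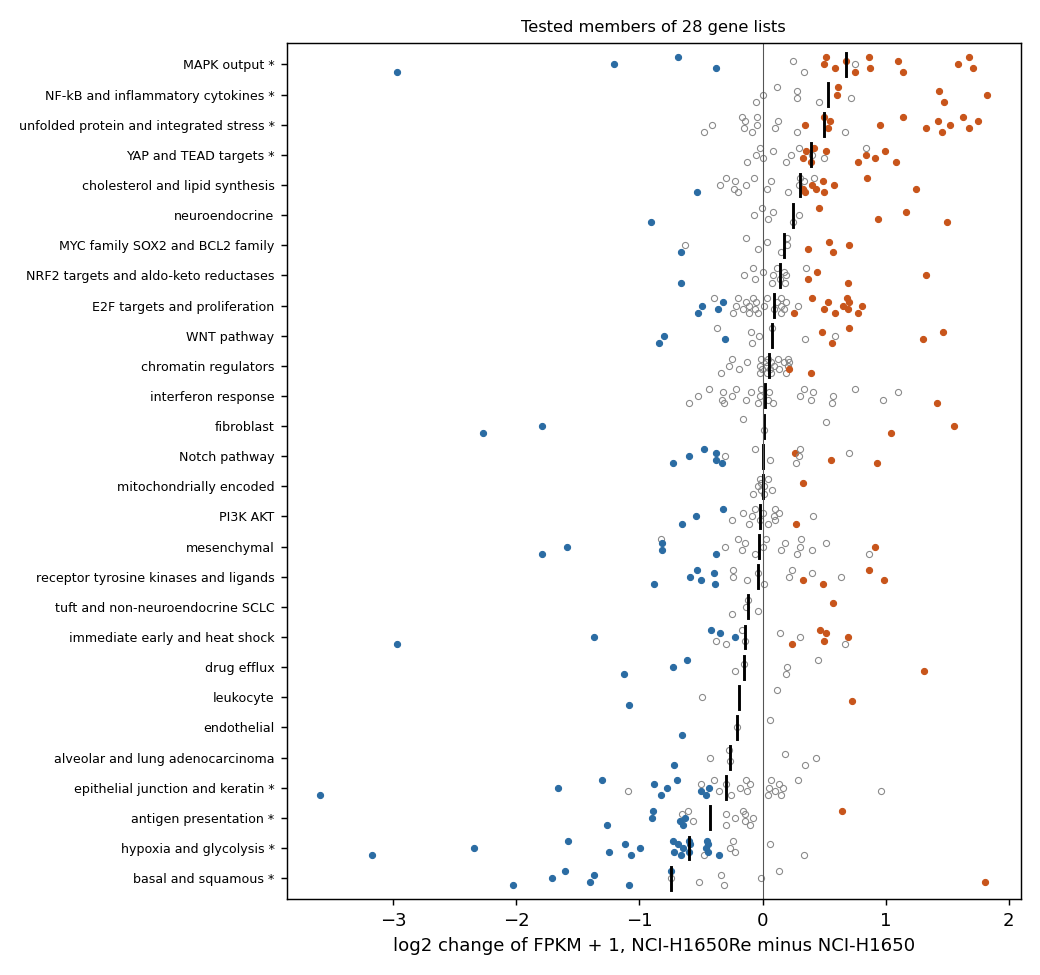
Log2 change of each tested member of 28 gene lists, on the horizontal axis, NCI-H1650Re minus NCI-H1650. Orange points rose, blue points fell and open grey points did not pass limma; black bars are list medians and an asterisk marks the 8 lists past camera at its preset correlation. Hypoxia and glycolysis genes sit mostly left of 0, with a median of -0.60.

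The neuroendocrine list had 11 tested members of 38, of which 4 rose, 1 fell and 6 did not pass, with the same counts adjusted over the list alone (median log2 change 0.25, limma camera adjusted p = 0.293). BEX1 rose from 6.25 ± 1.82 to 15.5 ± 5.66 FPKM and KIF5C, a neuronal kinesin, from 0.280 ± 0.0985 to 1.497 ± 0.598, beside CHGA. BEX1 missed the threshold without NCI-H1650 replicate 2 (limma adjusted p = 0.0508). Without both replicate 3 libraries, 7 of the 11 rose and 1 fell, and the list did not pass (limma camera adjusted p = 0.147). Among 5 tuft and non-neuroendocrine markers 1 rose, MYC (median log2 change -0.11, limma camera adjusted p = 0.677; adjusted over the list alone, 1). Its test pointed down with the median, against a mean of 0.01. Of 7 alveolar and lung adenocarcinoma genes, CAV1 fell from 165 ± 15.7 to 99.1 ± 5.26 and the other 6 did not pass (median log2 change -0.27, limma camera adjusted p = 0.593; adjusted over the list alone, 1). The mesenchymal list had 1 rise and 5 falls among 22 (adjusted over the list alone, 1 and 5; median log2 change -0.03, limma camera adjusted p = 0.293). Without both replicate 3 libraries 7 rose and 8 fell, and the list did not pass (limma camera adjusted p = 0.403). Over all libraries LOX fell from 6.16 ± 1.35 to 1.10 ± 0.641 and TWIST1 from 3.79 ± 0.442 to 0.653 ± 0.518. The members that fell thus included an inducer of mesenchymal transition. LOX lies in a run of chromosome 5 genes that were lower together.

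Cell-cycle genes went both ways. Of 37 E2F targets and proliferation genes 11 rose and 4 fell (adjusted over the list alone, 11 and 4; median log2 change 0.10, limma camera adjusted p = 0.503), with the mitotic kinases AURKA from 53.2 ± 5.34 to 94.1 ± 8.54 FPKM and BUB1 from 24.4 ± 2.91 to 42.6 ± 6.08. The Notch pathway had 3 rises and 6 falls among 16 (adjusted over the list alone, 5 and 7; median log2 change 0.00153, limma camera adjusted p = 0.503), with LFNG from 16.0 ± 1.07 down to 9.30 ± 0.540 and DTX1 from 0.327 ± 0.0651 up to 1.58 ± 0.604. In the MYC, SOX2 and BCL2 family list 4 rose and 1 fell among 12 (adjusted over the list alone, 6 and 2; median log2 change 0.17, limma camera adjusted p = 0.444); the survival factor BCL2L1 rose from 50.6 ± 4.66 to 82.8 ± 5.35 and the pro-apoptotic BCL2L11 fell from 13.5 ± 1.42 to 8.16 ± 0.548. For the Notch pathway the test pointed down, against a mean of 0.00854.

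Among 19 receptor tyrosine kinases and ligands 4 rose and 6 fell (adjusted over the list alone, 4 and 7; median log2 change -0.04, limma camera adjusted p = 0.503). The test pointed down with this list's median, against a mean of 0.01. KIT fell from 1.45 ± 0.178 to 0.330 ± 0.115 FPKM and EPHA2 rose from 34.7 ± 6.79 to 63.6 ± 8.10. The drug efflux list had 1 rise and 3 falls among 9 (adjusted over the list alone, 2 and 3; median log2 change -0.15, limma camera adjusted p = 0.356): the transporter ABCG2 rose from 3.67 ± 1.70 to 10.2 ± 1.67 and ABCC1 fell from 42.4 ± 0.734 to 18.9 ± 1.32, within a run of chromosome 16 genes that were lower together. In the WNT pathway 5 rose and 3 fell among 15 (adjusted over the list alone, 5 and 3; median log2 change 0.08, limma camera adjusted p = 0.675), with WNT5A from 3.92 ± 0.855 to 11.1 ± 1.44. Of 24 genes of the list cholesterol and lipid synthesis 9 rose and 1 fell (adjusted over the list alone, 10 and 3; median log2 change 0.30, limma camera adjusted p = 0.163). MVD rose from 17.5 ± 1.22 to 43.4 ± 9.65, inside a chromosome 16 run that was higher, and IDI1 from 16.4 ± 0.563 to 30.5 ± 5.12. This list passed limma camera without NCI-H1650Re replicate 3 (adjusted p = 0.0164) and without both replicate 3 libraries (0.0389). Both calls are at the preset correlation; over all 6 libraries it had limma camera adjusted p = 0.861 with an estimated correlation. NRF2 targets had 4 rises and 1 fall among 17 (adjusted over the list alone, 4 and 1; median log2 change 0.15, limma camera adjusted p = 0.163), with SLC7A11 from 3.28 ± 0.433 to 9.81 ± 2.03 and NQO1, within a lower chromosome 16 run, from 186 ± 6.28 down to 118 ± 13.98. PI3K and AKT genes had 1 rise and 3 falls among 17 (adjusted over the list alone, 0 and 3; median log2 change -0.02, limma camera adjusted p = 0.503), with PIK3R1 from 3.67 ± 0.331 down to 2.21 ± 0.244. Of 26 chromatin regulators 2 rose (adjusted over the list alone, 0; median log2 change 0.05, limma camera adjusted p = 0.675). Immediate early and heat shock genes had 5 rises and 5 falls among 17 (adjusted over the list alone, 5 and 5; median log2 change -0.14, limma camera adjusted p = 0.879), with FOS from 24.2 ± 10.2 down to 8.32 ± 1.38 beside EGR1.

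Interferon response genes differed more between libraries of a line than between the lines. Of 26 tested, 1 rose and none fell (adjusted over the list alone, 0; median log2 change 0.02, limma camera adjusted p = 0.909). In both lines replicate 3 was higher: the list's median deviation from the other libraries of the line was 1.59 in NCI-H1650 and 0.78 in NCI-H1650Re on the log2 scale, and 24 of 26 genes were above in both. MX1 was at 54.2, 82.9 and 323 FPKM in NCI-H1650 replicates 1, 2 and 3 and at 47.5, 94.98 and 193 in those of NCI-H1650Re. Without NCI-H1650 replicate 3 the list passed limma camera (adjusted p = 0.00321), and without both replicate 3 libraries 11 members rose and 2 fell (limma camera adjusted p = 0.0385). Both calls are at the preset correlation; over all 6 libraries the list had limma camera adjusted p = 0.983 with an estimated correlation. Lists of other cell types held few expressed genes. Of 7 fibroblast genes 2 rose and 2 fell (adjusted over the list alone, 3 and 2; median log2 change 0.01, limma camera adjusted p = 0.879), with COL3A1 from 10.1 ± 1.65 to 32.5 ± 10.05 and MXRA5 from 4.44 ± 1.30 to 0.107 ± 0.0473. Here the test pointed down with the mean, -0.16, against the median. Of 4 leukocyte genes CD14 fell from 1.56 ± 0.410 to 0.197 ± 0.0833, within a run of chromosome 5 genes that were lower together, and 1 rose (adjusted over the list alone, 1 rose and 2 fell), and of 3 endothelial genes TEK fell from 1.19 ± 0.214 to 0.393 ± 0.105 (adjusted over the list alone, 1); both lists were too small for the test. Of 10 mitochondrially encoded genes 1 rose (adjusted over the list alone, 0; median log2 change 0.00131, limma camera adjusted p = 0.954).

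The authors' deposited table marked 860 genes as regulated, 320 higher and 540 lower in NCI-H1650Re. Every marked gene had an FDR under 0.01 in the authors' deposited table and an absolute log2 fold change of at least 1. KRT19 had a log2 fold change of -3.48 in the authors' deposited table, against -3.59 on the log2(FPKM + 1) scale. Low genes differed more between the 2 scales: CA9 was at -6.59 in the authors' deposited table against -3.17, FAM133A at 5.88 against 2.82 and CHGA at 2.58 against 1.5. Of the 860 genes, 152 were below the expression filter used here; of the other 708, 689 passed limma, and 708 had the same sign. Conversely, 2988 of the 3587 genes that passed limma had an FDR under 0.05 in the authors' deposited table, and 3587 had the same sign. On the deposited counts of the 860 genes, edgeR and DESeq2 each called 860, with 320 higher and 540 lower by edgeR. These genes had been chosen by the authors on the same libraries, so the counts give no independent check of them.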

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

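The tests without both replicate 3 libraries, without genes in the shifted runs, with GC and length removed, and on rebuilt or deposited counts were chosen after the data were seen. Leaving out 1 library at a time gave 1785 to 4478 for genes changed, 899 to 2476 for genes higher in NCI-H1650Re and 886 to 2002 for genes lower in NCI-H1650Re; each lowest count came without NCI-H1650 replicate 2 and each highest without NCI-H1650Re replicate 3, and the cause was not tested. With an absolute log2 change of at least 1, a stricter threshold by construction, genes changed were 360, with 149 higher and 211 lower. Of the gene list tests, 0 passed with an estimated correlation, which was above the preset one for each of the 8 lists. Without both replicate 3 libraries 12 single key genes passed instead of 7; the cause was not tested. The authors' table calls fell to 249 at an absolute log2 fold change of at least 2 and to 325 at a group mean of at least 5 FPKM, both stricter by construction.

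The main test had been fixed beforehand without pairing by replicate number. Deviations of same-numbered libraries correlated at 0.17, -0.04 and 0.21, and not every library correlated best with its own number. With the replicate block, genes changed were 3522, and 8 lists and 7 key genes passed.

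All changes of sign were in genes that did not pass in the main test, and their cause was not tested. RB1 was at -0.000888 with median-of-ratios scaling, -0.00730 with quantile normalization, -0.0193 without both replicate 3 libraries, -0.00816 with edgeR and -0.00727 with DESeq2 on rebuilt counts. EZH2 was at -0.0126 with quantile normalization, and B2M at 0.17 without both replicate 3 libraries. With 1 library left out, log2 changes ran from -0.0211 to 0.0714 for RB1, -0.15 to 0.98 for VIM, -0.15 to 0.00245 for NOTCH1, -0.18 to 0.0605 for MYCL, -0.0435 to 0.0866 for EZH2 and -0.27 to 0.24 for B2M. For the 116 genes past the threshold under the naming rule, not all given above, 2042 comparisons kept direction and call, 126 lost the call and 0 reversed. For the 8 lists, 128 comparisons kept the call and 8 lost it. That tally leaves out fry and the estimated correlation, with which 0 lists passed. Without a variance trend only the single-gene test changed, so the list calls counted there repeat the main test. The test of gene lists among the authors' calls was not run, since values of all genes allowed camera, and DESeq2 on deposited counts was run only for the 860 genes that have them.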

Other observations

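The tests of gene families and of runs of neighbouring genes, and the bootstrap and Spearman values for the replicate 3 libraries, were chosen after the result was seen. Gene families sharing a symbol root were tested in the same way as the lists: of 190 families with at least 8 members, 0 passed limma camera with the preset or with an estimated correlation.

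Medians over 25 neighbouring genes passed the cutoff at 566 genes, in 16 stretches, of which 8 held at least 20 genes and the shortest 1 or 2, not all in the direction of their stretch. The longest lay on chromosome 16 from 31489471 to 81220370 (178 genes, median log2 change -0.56), followed by chromosome 10 from 5684838 to 31031937 (75 genes, 0.45) and chromosome 16 from 11249619 to 24572863 (68 genes, -0.81). No shuffle of gene order gave more than 28 called windows (permutation p = 0.000999), so chance order does not account for the total of 566. The shuffles tested this total only, so chance is not excluded for the short stretches. After GC content and transcript length were removed, 96.1% of called windows remained, so these do not account for most of them. A hypothesis is a DNA copy-number difference between the lines. Of 8 runs with at least 20 genes, 7 had 1 direction in all 9 pairs of libraries. The runs were picked for a shift between these same libraries, so 1 direction was likely whatever the cause. The hypothesis is left open, and no DNA was measured here. Shared regulation of neighbouring genes was not tested, and the run at chromosome 5 from 139475534 to 141651419 holds protocadherin genes that share exons.

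The fall of the hypoxia and glycolysis list did not rest on the runs, since only 1 of its 26 tested members lay in them. Leaving out run genes could therefore change little: the other 25 had a limma camera adjusted p of 4.20e-12 at the preset correlation. Over all 26 members the call was lost with an estimated correlation (limma camera adjusted p = 0.651). After GC content and transcript length were removed, the list's median log2 change was -0.62. Oxygen, cell density and medium at harvest are not given in the sources used here, and no biological explanation was tested.

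The replicate 3 libraries deviated in part alike in both lines. Over all tested genes their deviations correlated at 0.211. NCI-H1650 replicate 2 and NCI-H1650Re replicate 1, which share no number, correlated at 0.230. Deviations from a line's mean cancel out over its libraries, so these correlations depend on each other. The 0.230 is therefore no separate comparison for replicate 3. Over 1173 genes of at least 50 FPKM, where counting noise is small, the replicate 3 deviations correlated at 0.297 (Pearson, bootstrap SE 0.0510) and 0.147 (Spearman). Chance noise from lower depth would not be shared between the lines, so depth alone does not account for this correlation. Over genes with GC content and transcript length the Pearson correlation was 0.215 before and 0.252 after these were removed, so they do not account for it. In the interferon list 24 of 26 genes were above in both, while 31 of 37 E2F and proliferation genes were below in both. A shared day of culture or library making could not be tested, since the labels give no batch, and no biological explanation was tested.

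Of the 10 ways to split the 6 libraries into 3 and 3, 1 gave as many genes changed as the real split, the real split itself; the highest count of another split was 0. The same held for genes higher in NCI-H1650Re (1 of 10) and for genes lower in NCI-H1650Re (1 of 10). The other splits mixed both lines in each group, so the line difference added to the spread within groups and made gene calls unlikely. Their count of 0 therefore does not measure what chance alone would give. For the gene list tests, 5 of 10 splits gave at least as many lists as the real 8, and another split gave 10. With 10 splits no share can be under 0.05. The other splits held the 2 lines in unequal numbers, so they kept part of the line difference and of the replicate 3 deviations. Their list calls are therefore not those of groups without a difference. By this count the list calls at the preset correlation can be neither told from chance nor shown to be chance.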
